A study of Mus musculus with 9 samples.

How the data were processed

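Total RNA of mouse placenta at embryonic day 8.5 was labelled with Cy3 and hybridised to 9 one-colour Agilent arrays, 4 of wildtype and 5 of knockout for the Sfmbt2 microRNA cluster, per the labels' protocols. The arrays were read with Agilent Feature Extraction, per the submitters' processing notes, which name no version. The authors deposited 1 table of values on a log scale, taken here as log2, since neither the labels nor the values state the base. The background correction and the scaling between arrays are not given in the sources used here. The deposited log2 values are centred per probe: each of the 55681 probes had between 3 and 6 of its 9 values above 0, as the median over 12 arrays would give, of which 3 are not analysed here. What the baseline was is not stated. Because of the centring a probe's level is lost, so no probe can be called dim and the depth of signal over background is unknown. A fold is 2 to the power of the log2 difference and holds only if the base is 2.

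Probes were named with the table of platform annotation given with the values. Exactly 1 gene symbol was given for 30626 probes and none for 25055, and none had several. Of the named probes 30332 were matched by gene number to the RefSeq gene table of GRCm38.p6, which changed 0 symbols. The named probes made 21893 genes, of which 6807 had several probes. A gene's value was the mean of its probes, which was the rule fixed for values that had lost their level, and this hides probes that disagree.

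Group, replicate number and age were taken from the labels. For knockout replicate 5 the title and the source name give the number 5 and the description gives 4, and the title was followed. The labels do not say whether each array holds a separate placenta or litter, so p-values measure only the spread between these samples, which may be partly technical. No 2 arrays held equal values, and the highest correlation between 2 arrays of these centred values was 0.228. The genotype comparison (knockout minus wildtype) was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no further normalization, and adjusted by Benjamini-Hochberg over all genes at a threshold of 0.05. Gene lists were tested with limma's camera (competitive, two-sided) with its preset correlation of 0.01, over 29 lists with at least 4 measured genes, and again with the correlation estimated per list, under which none passed. The lists cover trophoblast types, placental gene families, tissues that could be carried over, imprinted genes, stress, growth and control genes. Single values were compared with an exact permutation test (two-sided) over the 126 splits of 9 arrays into 5 and 4.

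The main test, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The named genes were the 12 with the largest rise and the 12 with the largest fall among genes past the threshold, without clone, predicted or locus names, then Sfmbt2, then up to 4 members with the smallest p of each list named in the text and every member past the threshold where 5 or fewer passed. Which lists are described with their members was decided after the values were seen.

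The fit was tested on simulated arrays with the spread of the 21893 real genes and 200 changed genes. It recovered 37% of genes changed by a log2 difference of 1 and 73% of those changed by 2, and 8 of its 118 calls were false. The simulated genes were independent and each gene had the same spread in every array. The real arrays had weights from 0.21 to 1.96, so these rates need not hold for them. In a simulation of independent genes camera called the 1 shifted list and 0 of 28 others. Genes of the real lists are correlated, with an estimate of 0.92 for the visceral endoderm and yolk sac list. Random splits of the real arrays gave a median of 6 called lists, so the simulation does not show the rate of false list calls here.

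Alternatives were quantile normalization, centring on the median, shifting by the 75th percentile, the first-listed probe per gene, robust variance estimation, array weights (statmod 1.5.0), the replicate number as a block, each array left out in turn, the probe level and a minimum fold of 1.5. After the data were seen, 4 were added, which were leaving out wildtype replicate 1 and knockout replicate 5 together, the yolk sac list mean as a covariate, the level of the Y-linked gene Eif2s3y as a covariate, and a threshold of 0.10. The planned filters on dim probes, the floor and the intensity trend need a probe's level and were not run. The planned test of microRNA seed sites needs 3' UTR sequences, which were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.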

Results

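Messenger RNA of mouse placenta at embryonic day 8.5 was measured on one-colour Agilent arrays. The placentas came from embryos made by in vitro fertilization and carried by foster mothers, and the decidua, the maternal lining around the implant, had been removed. Wildtype placentas (4 arrays) were compared with placentas lacking the microRNA cluster that lies in an intron of the imprinted gene Sfmbt2 (5 arrays, called knockout here). The deposited values were logarithms, taken as log2, centred probe by probe, so that they show how an array stood against the others and not how strongly a gene was expressed. Array medians ran from -0.18 in wildtype replicate 1 to 0.16 in knockout replicate 5, and the number of arrays limits the precision. The series was designed to find genes that the microRNAs of the cluster act on.

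Sfmbt2 itself, the host gene of the cluster, had a mean of -0.02 ± 0.16 (SD, n = 4) in wildtype and -0.33 ± 0.33 (SD, n = 5) in knockout. The log2 difference of -0.32 (SE 0.18) did not pass limma's moderated test (adjusted p = 0.357). The wildtype values were -0.20, -0.08, 0.15 and 0.07, and the knockout values -0.35, -0.69, -0.49, 0.21 and -0.33. An exact permutation test of the 2 means (two-sided) gave p = 0.119. Its 3 probes gave log2 differences of -0.65, 0.18 and -0.47. Their unadjusted p in limma's moderated test at probe level was 0.0117, 0.374 and 0.0431, and none passed after adjustment (adjusted p from 0.222 to 0.634). The positions of the probes were not looked at. A probe for the messenger RNA would lie outside a deleted intronic cluster, so these values are not taken as a check of the genotype.

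Which genes differ between the genotypes was asked first. Of 21893 genes, 15 rose and 4 fell in the knockout placenta. The gene with the largest rise was Ocm, which encodes the calcium-binding protein oncomodulin. Its mean went from -0.29 ± 0.36 (SD, n = 4) to 2.13 ± 0.46 (SD, n = 5), a 5.36-fold rise (log2 difference 2.42, SE 0.26, adjusted p = 0.0184). The ion channel gene Pkd2l1 rose 4.60-fold (SE 0.20 on the log2 scale, adjusted p = 0.0166). Lrg1, which encodes a secreted leucine-rich glycoprotein, rose 4.49-fold, and the kelch-domain gene Klhdc9 rose 4.34-fold. Tpbpb, a trophoblast-specific gene of the spongiotrophoblast, rose 3.56-fold (log2 difference 1.83, SE 0.24, adjusted p = 0.0418).

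A further 6 genes rose between 2.68-fold and 3.11-fold. They were Tbx1, a T-box transcription factor (log2 difference 1.64), Reps2, an endocytic adaptor (1.63), Il27ra, the receptor for interleukin 27 (1.54), Dtx1, a regulator of Notch signalling (1.54), Tmprss6, the protease matriptase-2 (1.45), and Wdr27 (1.42). Herpud1, which acts in degradation at the endoplasmic reticulum, rose 1.98-fold (adjusted p = 0.0184). It had the smallest standard error among the named genes past the threshold over all genes, 0.11. The remaining 3 genes that rose fell outside the rule for named genes and were picked out after their values were seen. They were the collagen chaperone gene Serpinh1 (log2 difference 0.89), the formin gene Daam1 (0.81) and the clone-named 1700001J03Rik (1.53).

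The 4 genes that fell were Zfp277, a zinc-finger gene, Itln1, which encodes the lectin intelectin, Trim59, and the myosin motor gene Myo5a. Zfp277 fell by 2.21 on the log2 scale (SE 0.22, adjusted p = 0.0184), from 0.45 ± 0.53 (SD, n = 4) to -1.76 ± 0.07 (SD, n = 5). Its wildtype values lay in 2 pairs, at -0.04 and 0.04 and at 0.93 and 0.89. Itln1 fell by 2.11, Trim59 by 1.58 and Myo5a by 1.22. The probes of 2 of these genes gave different sizes, with -2.74 and -0.41 for Trim59 and -0.93, -2.32 and -3.08 for Itln1.

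**Figure D1:**
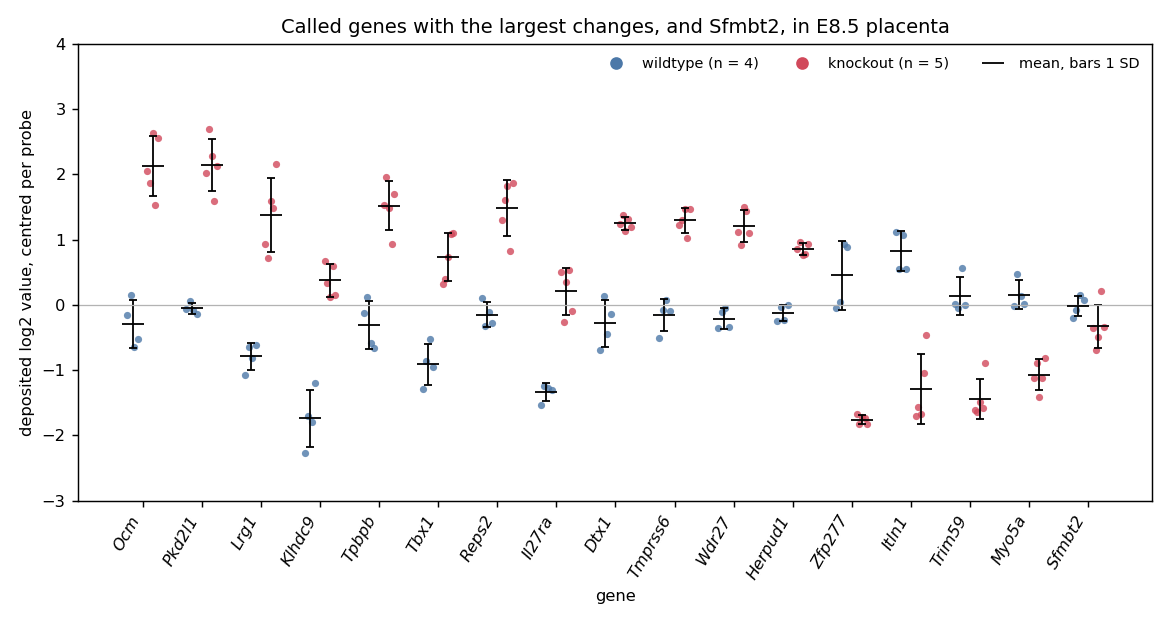
Deposited log2 value (vertical axis, centred per probe) of the 16 named genes past adjusted p 0.05 and of Sfmbt2, with 1 point per array, the group mean as a line and 1 SD as a bar, for wildtype (n = 4) and knockout (n = 5). The groups do not overlap for any of the 16 genes, from Ocm (log2 difference 2.42) to Zfp277 (-2.21), while they overlap for Sfmbt2.

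The test was limma's moderated test with Benjamini-Hochberg adjustment over all genes. In all 19 genes every knockout array lay on one side of every wildtype array, but the genes were selected on that difference, so this is no separate evidence (1.59% of genes not selected in this way would show it by chance). At an unadjusted p under 0.05 there were 4603 genes, and 3457 of them were higher in knockout. A share of 0.05 of all genes would be 1095, but that number does not allow for genes that move together. The count at an unadjusted p was not taken in random splits of the arrays, so its excess over 1095 is not established. It was 2858 without knockout replicate 4 and 6257 under quantile normalization. The calls stood close to the threshold. Without wildtype replicate 1, or with the replicate number as a block over 8 arrays, 0 genes passed. Between 1 and 10 passed without any other array but knockout replicate 5, of which between 0 and 8 were among the 19. With array weights 1040 passed, 448 higher and 592 lower. Centring each array on its own median gave 18 genes higher and 23 lower in place of 15 and 4. The balance between rises and falls thus depends on the scaling and on the weight given to single arrays. The sign of all 19 genes was the same in both settings.

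The comparison of 29 gene lists, chosen from textbook knowledge of the placenta, asked which cell types and processes moved. The median log2 difference over all genes was 0.08, and it went to -0.05 under quantile normalization. List medians are therefore also given relative to that of all genes.

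Genes of the parietal endoderm, the layer that secretes the basement membrane around the conceptus, were higher in knockout. Of 14 measured members 13 had positive differences, with a median of 0.55, which is 0.46 above that of all genes (camera, adjusted p = 3.29e-04, but adjusted p = 0.852 with an estimated correlation). No member passed over all genes, and 8 passed adjusted over the list alone. The 4 with the smallest p were the basement membrane collagens Col4a2 (0.74, SE 0.17) and Col4a1 (0.69, SE 0.18), the transcription factor Sox7 (0.69, SE 0.17) and the plasminogen activator Plat (0.93, SE 0.23). The list mean was -0.33 ± 0.31 (SD, n = 4) in wildtype and 0.17 ± 0.08 (SD, n = 5) in knockout, and an exact permutation test (two-sided) gave p = 0.0159, or 0.23 adjusted over the 29 lists.

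Genes of the endoplasmic reticulum stress and amino acid response were higher in knockout, with positive differences in 12 of 14 members and a median of 0.25, which is 0.17 above that of all genes (camera, adjusted p = 0.0198, but adjusted p = 0.852 with an estimated correlation). Herpud1 passed over all genes, and 5 members passed adjusted over the list alone. These were Herpud1, the pseudokinase gene Trib3 (log2 difference 1.59, SE 0.29), the cystine transporter gene Slc7a11 (0.72, SE 0.20), the transcription factor Atf3 (0.70, SE 0.22) and Ddit4 (0.76, SE 0.26). The list mean of every knockout array, from 0.07 to 0.37, lay above that of every wildtype array, from -0.42 to -0.03. The exact permutation p of 0.0079 is the smallest that 126 splits can give, and it came to 0.23 adjusted over the lists. The camera call ended under quantile normalization (median 0.15, adjusted p = 0.0781) and with arrays centred on the median (0.16, adjusted p = 0.0545) or shifted by the 75th percentile (0.088, adjusted p = 0.108). Relative to all genes the median was 0.19 under quantile normalization. The other 2 scalings move all genes of an array alike, so the 0.17 could not change there. The call also ended without wildtype replicate 1 (adjusted p = 0.0829), knockout replicate 2 (0.062), or wildtype replicate 1 and knockout replicate 5 together (0.0511). The median was 0.45 without wildtype replicate 2 and 0.15 with array weights.

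The placental cathepsins and serpins, proteases and protease inhibitors made by trophoblast, were higher in knockout. Of 16 members 14 had positive differences, with a median of 0.56, which is 0.48 above that of all genes (camera, adjusted p = 0.00682, but adjusted p = 0.852 with an estimated correlation). None passed over all genes. Adjusted over the list alone 4 passed, which were Ctsm (log2 difference 1.54, SE 0.46), Serpinb9e (0.54, SE 0.16), Serpinb9f (0.52, SE 0.15) and Serpinb9g (0.52, SE 0.15). The list mean was -0.13 ± 0.52 (SD, n = 4) in wildtype and 0.65 ± 0.44 (SD, n = 5) in knockout, with an exact permutation p of 0.0714. Without wildtype replicate 1 and knockout replicate 5 together the median was 0.35.

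The pregnancy-specific glycoproteins and Ceacam genes, a family of immunoglobulin-like proteins secreted by trophoblast or held on its surface, were higher in 18 of 21 members. The median was 0.60, which is 0.51 above that of all genes (camera, adjusted p = 0.0192, but adjusted p = 0.852 with an estimated correlation). No member passed over all genes, and Ceacam5 passed adjusted over the list alone (log2 difference 3.46, SE 0.75, or 2.83 without knockout replicate 2). The next were Ceacam9 (0.59, SE 0.21), Ceacam12 (0.88, SE 0.36) and Psg16 (0.60, SE 0.25). The call ended without wildtype replicate 1 (adjusted p = 0.0829), without knockout replicate 1 (0.0531) and without knockout replicate 2 (0.0985). Members of these families, of the serpins, of the prolactins and of the granzymes are similar in sequence, and a probe can bind the transcript of a relative, so the values of single members are uncertain.

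Genes of uterine natural killer cells, maternal lymphocytes of the implantation site, were lower in knockout. Of 13 members 10 had negative differences, with a median of -1.34, which is -1.42 relative to all genes (camera, adjusted p = 0.00682, but adjusted p = 0.852 with an estimated correlation). None passed over all genes, and 2 passed adjusted over the list alone, the perforin gene Prf1 (-1.15, SE 0.28) and the granzyme gene Gzma (-2.74, SE 0.77). The receptor genes Klrk1 (0.57, SE 0.21) and Klrb1c (0.85, SE 0.32) had differences of the opposite sign. Knockout replicate 5 had a list mean of -2.66, against -0.34 to 0.68 in the other knockout arrays and 0.30 to 1.10 in wildtype. Without it the median was -0.81 and Gzma was at -2.05. The call ended under the 3 scalings between arrays (adjusted p from 0.0886 to 0.164), with medians of -1.59, -1.44 and -1.51. Relative to all genes the median was -1.54 under quantile normalization. The other 2 scalings move all genes of an array alike, so the -1.42 could not change there. The leukocyte and macrophage list had negative differences in 11 of 13 members, with a median of -0.23 that did not pass (camera, adjusted p = 0.0927), and knockout replicate 5 was lowest in it too, at -0.74. Without knockout replicate 5 the median of the leukocyte list was -0.12 (adjusted p = 0.484). With quantile, median and 75th-percentile scaling it was -0.39, -0.32 and -0.39, and the list did not pass (adjusted p from 0.277 to 0.345). The leukocyte list passed without wildtype replicate 3 (median -0.47, adjusted p = 0.0064) and without knockout replicate 4 (-0.35, adjusted p = 0.0297). Without wildtype replicate 4 its median was -0.38 (adjusted p = 0.0939).

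Cell cycle genes were lower in knockout by a small amount. Of 24 members 21 had negative differences, with a median of -0.21, which is -0.29 relative to all genes (camera, adjusted p = 3.29e-04, but adjusted p = 0.852 with an estimated correlation). None passed over all genes or adjusted over the list alone. The members with the smallest p were the cyclin genes Ccne1 (-0.48, SE 0.14) and Ccna2 (-0.27, SE 0.11), the survivin gene Birc5 (-0.42, SE 0.17) and, in the other direction, the cyclin gene Ccnd1 (0.67, SE 0.26). Knockout replicate 5 had the highest list mean of all arrays, 0.27, against -0.33 to -0.14 in the other 4 knockout arrays, and the exact permutation p of the list mean was 0.397. The median was -0.33 under quantile normalization and -0.37 with arrays shifted by the 75th percentile.

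**Figure D2:**
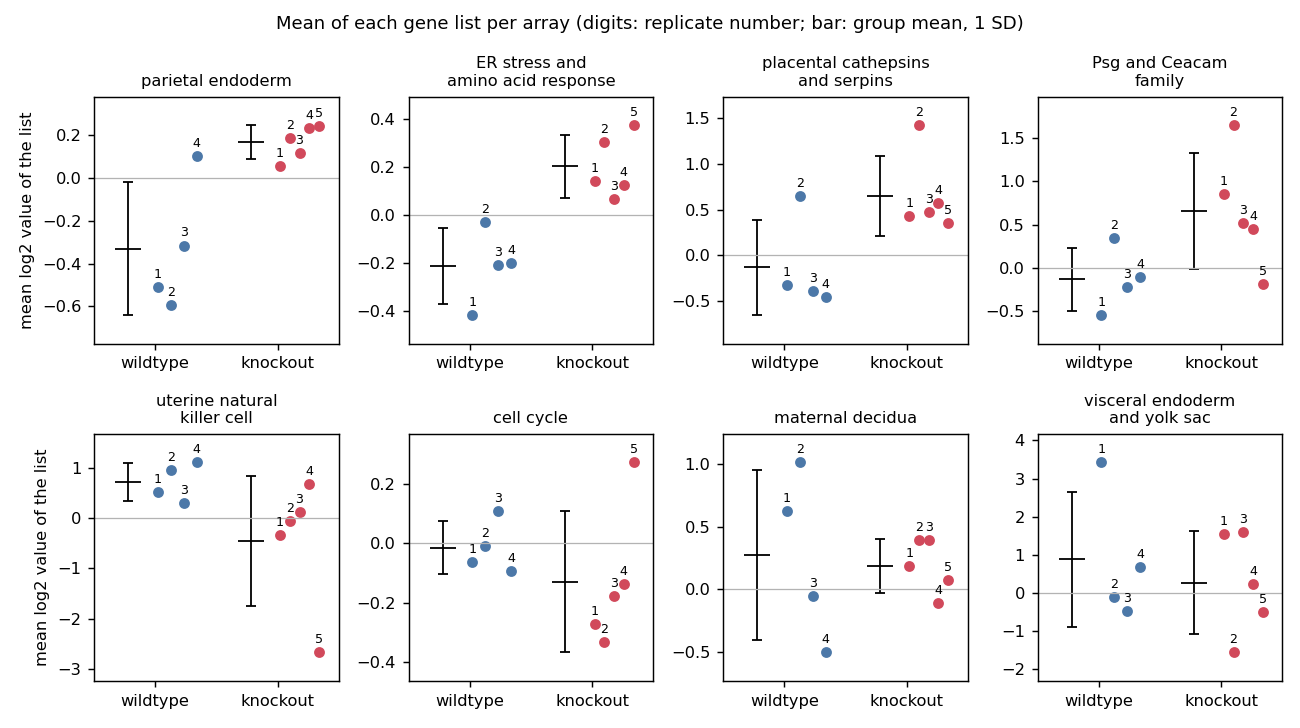
Mean log2 value of 8 gene lists (vertical axis) in each wildtype (n = 4) and knockout (n = 5) array, with the replicate number above each point and the group mean and 1 SD to its left. The groups are apart for the endoplasmic reticulum stress list (0.07 to 0.37 against -0.42 to -0.03), knockout replicate 5 is far down in the natural killer cell list (-2.66), and wildtype replicate 1 is far up in the yolk sac list (3.42).

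As many as 6 lists past the threshold were also reached when the same 9 arrays were split at random into 5 and 4, in 53 of 100 splits with the real one included. The number of list calls thus does not exceed what other groupings of these arrays give.

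Lists of trophoblast cell types did not pass as groups. For the ectoplacental cone and spongiotrophoblast the median was 0.27 (camera, adjusted p = 0.206). Tpbpb passed over all genes, and Tpbpa (log2 difference 2.23, SE 0.39), Flt1 (1.14, SE 0.24) and Prl7a2 (0.68, SE 0.20) passed with it adjusted over the list alone. The placental prolactin family had a median of 0.21 (adjusted p = 0.268), and 4 of its 20 members passed adjusted over the list alone, which were Prl2b1 (2.08, SE 0.34), Prl7c1 (0.99, SE 0.21), Prl6a1 (0.70, SE 0.17) and Prl7a2. Both lists passed without knockout replicate 5, with medians of 0.57 (adjusted p = 0.0334) and 0.25 (adjusted p = 0.0233). They share prolactin genes, and 15 of 19 and 17 of 20 members are also in other lists, so these are not independent results. Without 1 array their medians ran from 0.14 (without knockout replicate 2) to 0.57 and from 0.089 (without knockout replicate 4) to 0.31 (without wildtype replicate 2). Both also passed with the replicate number as a block (0.0295 and 0.0149), which leaves out knockout replicate 5. Without wildtype replicate 1 and knockout replicate 5 together the prolactin family passed (median 0.25, adjusted p = 0.0483). The ectoplacental cone list did not pass there (0.49, adjusted p = 0.0963). The glycogen trophoblast list had a median of 0.28 (adjusted p = 0.322), or 0.19 without knockout replicate 5, with Prl6a1, Aldh1a3 (2.73, SE 0.87) and Pcdh12 (0.56, SE 0.18) past the threshold adjusted over the list alone. Wildtype replicate 4 was at -4.51 for Aldh1a3, and without that array the difference was 1.73. Of the labyrinth and syncytiotrophoblast list, with a median of 0.24 (adjusted p = 0.236), 1 member passed in that way, the syncytin gene Syna (1.47, SE 0.36). Without knockout replicate 5 the median of that list was 0.057. None of the 11 measured members of the trophoblast giant cell list passed, and its median of 0.11 (adjusted p = 0.676) was negative under quantile normalization (-0.03) and with arrays shifted by the 75th percentile (-0.06). Without 1 array it was between 0.034 (without knockout replicate 2) and 0.23 (without knockout replicate 5). Under the 3 scalings between arrays the medians of the other 4 lists were between 0.040 and 0.19.

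**Figure D3:**
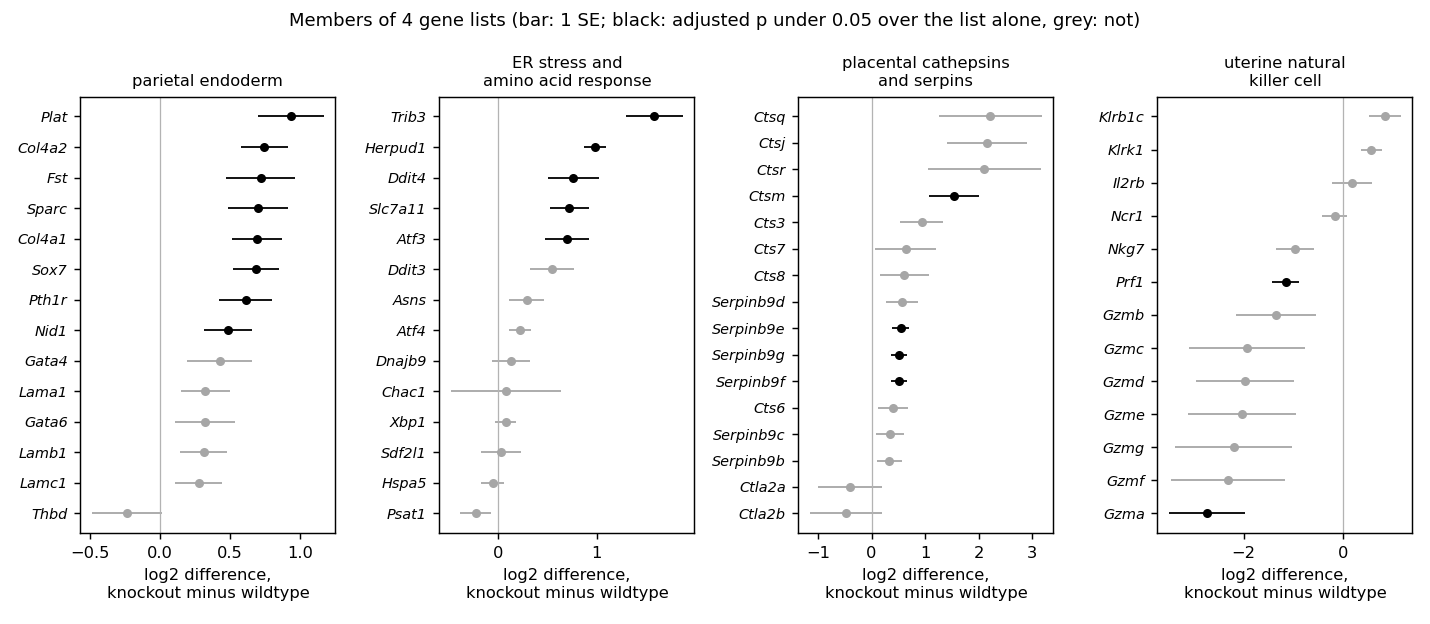
Log2 difference, knockout minus wildtype (horizontal axis), of each measured member of 4 gene lists with 1 SE as a bar, from 4 wildtype and 5 knockout arrays. Members past adjusted p 0.05 over the list alone are black, which are 8 of 14 for parietal endoderm, 5 of 14 for endoplasmic reticulum stress, 4 of 16 for cathepsins and serpins and 2 of 13 for natural killer cells.

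Tissues that can be carried over in dissection were followed with their own lists. Genes of the visceral endoderm and yolk sac had a median of -0.61 that did not pass (camera, adjusted p = 0.0689), and the list mean was 3.42 in wildtype replicate 1 against -1.56 to 1.59 in the other arrays. The median was 0.20 without wildtype replicate 1 and -0.13 without knockout replicate 2. The list passed as lower, with medians from -1.10 to -0.69, without wildtype replicate 2 (adjusted p = 0.00694), wildtype replicate 3 (0.00171), wildtype replicate 4 (0.0478), knockout replicate 1 (0.00713) or knockout replicate 3 (0.00446). The members with the smallest p were the plasma protein and lipoprotein genes Fgb (-1.38, SE 1.09), Apob (-1.08, SE 1.12), Apom (-1.08, SE 1.13) and Apoc2 (-1.02, SE 1.09), which were at -0.43, -0.04, -0.15 and -0.18 without wildtype replicate 1. Genes of the maternal decidua had a median of 0.03 and a mean of -0.08 (adjusted p = 0.59), and the median was between -0.31 (without wildtype replicate 4) and 0.27 (without wildtype replicate 2) without 1 array, so no direction is given. The members with the smallest p were Prl8a2 (-1.07, SE 0.40), Esr1 (0.64, SE 0.29), Wnt4 (0.48, SE 0.25, or 0.27 and 0.74 without wildtype replicates 1 and 2) and Cryab (-0.54, SE 0.31, or -0.18 without wildtype replicate 2).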

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

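The tests in this part were chosen after the values were seen, except the count of other splits of the arrays and the second list of visceral endoderm genes, which were set before their results.

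The genotype calls were set against other splits of the same arrays. Of 100 splits of the 9 arrays into 5 and 4, drawn at random with the real one included, 1 gave as many as 19 genes past adjusted p 0.05, which was the real one, and the highest of the others gave 1 gene. So large a number of genes was thus rare among other groupings of these arrays, but 100 draws cannot exclude chance. The splits also take the arrays as separate samples, which the labels do not state. Without wildtype replicate 1, or with the replicate number as a block, 0 genes passed. For the gene lists 53 of the 100 splits gave as many as the 6 of the real split, and the highest other split gave 16, so chance cannot be excluded for the number of lists.

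Genes of uterine natural killer cells were lower in knockout, with a median of -1.34, although the decidua that holds these cells had been removed. Less decidual tissue in the knockout samples cannot be judged from the maternal decidua list. Its median was 0.027, with quartiles from -0.27 to 0.28, but that median ran from -0.31 to 0.27 without 1 array. Its members were split, with 8 positive, such as Esr1 (0.64), and 8 negative, such as Prl8a2 (-1.07). Of its 16 members 1, Prl8a2, is also in another list. Less decidual tissue thus stays open. The lower values were not confined to knockout replicate 5. Without that array the median was -0.81 with an interquartile range of 0.72, against 0.06 for all genes. Of the 13 members 10 were still negative. Several members are granzymes of similar sequence whose probes can share a signal, so that count and that range do not come from independent genes. Knockout replicate 4, with a list mean of 0.68, lay within the wildtype range of 0.30 to 1.10. The genotype stays open as a candidate explanation, since the exact permutation p of the list mean was 0.0794, and so does a difference in the number or the state of these cells left after dissection.

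Genes of the visceral endoderm and yolk sac were high in wildtype replicate 1. All 16 measured members had their highest value there, and a second list of 15 visceral endoderm genes, none of them in the first, was then tested. All 15 were highest in that array, among them Serpina1a (4.92), Serpinf2 (4.29) and Cldn2 (4.09), which is consistent with yolk sac tissue in that sample. The level of its abundant transcripts is lost with the centring, so no share of tissue can be estimated. A shift of that whole array upwards is argued against, since its median of -0.18 was the lowest of all arrays. The list mean there was 3.60 after every array was centred on its median, against 1.67 in the next array. That centring could only raise the list mean of this array, and it cannot judge a scaling that changes the spread of the values. With 1 sample involved, no biological explanation was tested.

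More genes were higher than lower in knockout, 75.1% of those with an unadjusted p under 0.05. The share was 49.3% after every array was centred on its median, but that centring itself draws the share towards an even one and so decides nothing. The 75th percentile of all probes was 0.42 and 0.62 in knockout replicates 4 and 5, against 0.04 to 0.13 in the other arrays. With array weights and no rescaling, 43.1% of the genes past adjusted p 0.05 were higher. The authors' scaling is not stated, and the exact permutation p of the array medians was 0.238. Scaling between arrays and a true excess of rises in the knockout thus cannot be told apart.

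Single arrays stood apart from the rest of their group by Dixon's test in 18 of 228 groups of 4 or 5 arrays looked at, where chance gives about 1 in 20, or 11.4. Among genes, Trim59 was at 0.56 in wildtype replicate 3 (others -0.04 to 0.02) and at -0.90 in knockout replicate 5 (others -1.63 to -1.48). Flt1 was at 0.13 in wildtype replicate 1 (others -0.57 to -0.50) and Pcdh12 at 1.03 in knockout replicate 5 (others 0.23 to 0.37). Tfeb, a labyrinth gene, was at 0.41 in wildtype replicate 4 (others -0.42 to -0.28). Serpinb9f was at -0.63 in wildtype replicate 1 (others -0.08 to 0.02) and Serpinb9e at 0.28 in knockout replicate 5 (others 0.33 to 0.35). The imprinted gene Usp29 was at -1.54 in wildtype replicate 4 (others -0.11 to 0.08).

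Among list means, the placental cathepsins and serpins were at 0.64 in wildtype replicate 2 (others -0.46 to -0.33) and at 1.42 in knockout replicate 2 (others 0.35 to 0.58). Knockout replicate 5 stood apart in 4 lists, with -0.55 for erythroid genes (others 0.31 to 0.44), 0.62 for hypoxia and glycolysis (others -0.35 to -0.11), 0.044 for Polycomb (others -0.10 to -0.07) and 0.34 for housekeeping genes (others -0.17 to -0.04). Endothelium and allantois genes were at -0.54 in wildtype replicate 4 (others 0.03 to 0.09). Interferon response genes were at -0.0006 in wildtype replicate 2 (others -1.06 to -0.95), and immediate early and heat shock genes at -0.67 in wildtype replicate 1 (others -0.11 to -0.02). The 25th percentile of all probes was -0.49 in wildtype replicate 1 (others -0.27 to -0.24). Of these 18 values 7 were of knockout replicate 5 and 4 of wildtype replicate 1.

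Of the 25055 probes with no gene symbol, which no gene-level comparison used, 9 passed adjusted p 0.05 between knockout and wildtype in the fit at probe level, 5 higher and 4 lower.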

How the results depend on the processing

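Leaving out wildtype replicate 1 and knockout replicate 5 together, the yolk sac and Eif2s3y covariates and threshold 0.10 were chosen after seeing the data. Against 19 genes as reported, limma called 36 with quantile normalization (16 shared with the 19), 41 with arrays centred on the median (18 shared) and 1040 with array weights (19 shared). It called 2 without wildtype replicate 1 and knockout replicate 5 together (0 shared), 12 with the yolk sac covariate (10 shared), 2 with the Eif2s3y covariate (2 shared) and 72 at adjusted p under 0.10. The 75th percentile gave 17 (10 shared), the first-listed probe 13 (13), and robust estimation and the 1.5-fold minimum 19 each (19). At probe level 23 probes passed (9 unnamed), covering 11 of the 19 genes. The share of higher genes was 78.9% as reported. It was 41.7%, 43.9% and 41.2% with quantile, median and 75th-percentile scaling, and 43.1% with array weights. The count was 0, 5, 1 and 3 without wildtype replicates 1 to 4 in turn. It was 1, 6, 2, 10 and 23 without knockout replicates 1 to 5. Where 0 genes passed without wildtype replicate 1, 3018 had an unadjusted p under 0.05. The sign of all 19 genes was kept in the 19 gene-level settings, and the median ratio of their log2 differences to those reported lay between 0.85 and 1.02. Calls thus ended with little change in size where an array was left out, which leaves fewer samples. For the other settings the cause was not tested.

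Same-numbered wildtype and knockout arrays correlated at 0.20, 0.305, -0.02 and 0.194 after removal of the group means. Arrays of unlike number correlated at -0.25 to 0.26. Knockout replicates 1, 2 and 4 each correlated best with the wildtype of their own number, while knockout 3 did so with wildtype 1 (0.26). Whether the numbers pair the samples is thus not settled, and the main fit did not pair them. With the number as a replicate block, over 8 arrays, 0 genes (5283 at an unadjusted p under 0.05) and 11 lists passed.

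Of the lists, 6 passed as reported, 0 with an estimated correlation, 10 without wildtype replicate 1 and knockout replicate 5 together, and 4 to 10 without 1 array. Parietal endoderm, cathepsins and serpins, and cell cycle passed in every setting run but the estimated correlation. Sfmbt2 stayed negative and did not pass in any gene-level setting, although 1 of its 3 probes was at 0.18.

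The direction of camera's test turned for 9 lists in some setting, with 30 list values in all and no call on either side, and the cause was not tested. The medians were, for maternal decidua, 0.18 with array weights and 0.21 without wildtype replicate 1 and knockout replicate 5 together (-0.31 to 0.27 without 1 array), and for visceral endoderm and yolk sac 0.10 and 0.35 (-1.10 to 0.20). For embryo proper they were -0.13 with quantile normalization, -0.13 with the 75th percentile, -0.045 with array weights, 0.043 with the block, -0.017 without both arrays, -0.0022 with the yolk sac covariate and 0.085 with Eif2s3y (-0.019 to 0.13 without 1 array). For p53 targets and apoptosis the median was 0.057 with array weights (-0.008 to 0.094), and for tumour suppressors -0.028, -0.015 and -0.084 with quantile, median and 75th-percentile scaling (0.070 to 0.12). Without 1 array the medians ran from -0.097 to 0.11 for trophoblast stem and chorion, 0.034 to 0.23 for trophoblast giant cell, 0.11 to 1.32 for erythroid and 0.084 to 0.16 for imprinted genes. In these lists the test, which compares with all other genes, can turn while the median keeps its sign. In 2 further lists the median turned and the list was then called lower, the test having had that direction throughout: hypoxia and glycolysis went from 0.04 to -0.16 without knockout replicate 5 (adjusted p = 0.0367), -0.16 with the block (0.0497) and -0.18 without both arrays (0.0241), and housekeeping from 0.02 to -0.17 without both arrays (0.0367). Without both arrays Apob was at 0.32, Apom at 0.077 and Apoc2 at 0.028. Signal over background cannot be judged, since the values are centred. The filters on dim probes, the floor, the intensity trend and the seed-site test with all its alternatives were not run.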

Other observations

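Other gene groups were looked at beyond those of the genotype comparison above, and the member genes named here follow the same rule. The choice of lists described with their members, the setting without both arrays and the test of neighbouring genes were made after the values were seen. Interferon response genes had positive differences in 9 of 10 measured members, with a median of 0.83 (camera, adjusted p = 0.0927), and Rsad2, the antiviral protein viperin, passed adjusted over the list alone (log2 difference 1.32, SE 0.32). Irf7 (1.30, SE 0.41), Oas1a (0.62, SE 0.22) and Isg15 (1.72, SE 0.63) did not. Without knockout replicate 2 the median was 0.52 (adjusted p = 0.489). The list passed without wildtype replicate 2 (median 1.16, adjusted p = 0.00734) and without knockout replicate 5 (median 1.25, adjusted p = 0.00677). It also passed with array weights (0.0382), with the replicate block (3.55e-04) and without wildtype replicate 1 and knockout replicate 5 together (0.022). Among 36 imprinted genes, whose median was 0.13 (adjusted p = 0.655), the transporter gene Slc22a18 passed adjusted over the list alone (1.14, SE 0.24), while Usp29 (1.28, SE 0.33), Nap1l5 (0.70, SE 0.30) and Zim1 (0.63, SE 0.33) did not. The median of the imprinted genes was -0.01 under quantile normalization and -0.04 with arrays shifted by the 75th percentile, and 0.084 without knockout replicate 2.

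Erythroid genes had a median of 0.71 (adjusted p = 0.582), with Klf1 at 1.29 (SE 0.76, or 0.61 without wildtype replicate 4), the embryonic globin gene Hbb-bh1 at 0.83 (SE 0.51, or 0.25 without that array), Epor at 0.82 (SE 0.55, or 0.34 without it and 1.32 without wildtype replicate 1) and Hemgn at -0.93 (SE 0.25). The list passed without wildtype replicate 1 and knockout replicate 5 together (median 1.31, adjusted p = 0.00453) and with array weights (1.07, adjusted p = 0.0426). Its median was 1.32, 0.41, 1.10 and 0.11 without wildtype replicates 1, 2, 3 and 4. Endothelium and allantois genes had a median of 0.24 (adjusted p = 0.268), which was 0.089 without wildtype replicate 4 and 0.37 without wildtype replicate 1. The list passed with array weights (0.42, adjusted p = 0.0426) and with the replicate block (0.33, adjusted p = 0.0276). Polycomb genes had a median of -0.13 (adjusted p = 0.105), or -0.19 without wildtype replicate 2. Immediate early and heat shock genes had a median of 0.19 (adjusted p = 0.59), with 0.092 without knockout replicate 5, 0.10 without wildtype replicate 1, 0.31 without wildtype replicate 2 and -0.0075 with array weights. Under the 3 scalings between arrays the medians were 0.072 to 0.14 for endothelium, -0.29 to -0.22 for Polycomb and 0.028 to 0.098 for immediate early genes. Sex-linked genes had a median of -0.03 (adjusted p = 0.582), which was -0.62 without wildtype replicate 3, -0.31 without wildtype replicate 1, 0.06 without wildtype replicate 2, between -0.29 and -0.16 without any other array, and -0.39 under quantile normalization. That list joins Xist with Y-linked genes. Xist and the Y-linked gene Eif2s3y had opposite signs in every array, so the list's median and test cannot judge a difference in sex. Medians under 0.1 in size were found for trophoblast stem and chorion (-0.003, adjusted p = 0.582), embryo proper (0.04, adjusted p = 1), tumour suppressors (0.08, adjusted p = 0.744), p53 targets and apoptosis (0.02, adjusted p = 0.818), hypoxia and glycolysis (0.04, adjusted p = 0.655, but -0.16 and adjusted p = 0.0367 without knockout replicate 5), the microRNA pathway (-0.04, adjusted p = 0.582), the neighbours of Sfmbt2 on its chromosome (-0.01, adjusted p = 0.655) and housekeeping genes (0.02, adjusted p = 0.582). Without 1 array the medians of these 8 lists were between -0.16 and 0.13, and under the 3 scalings between -0.21 and -0.015. Of their members 3 passed adjusted over the list alone and none over all genes. They were the tumour suppressor gene Pdcd4 (log2 difference 0.91, SE 0.18), the p53 target Btg2 (0.85, SE 0.18) and the Argonaute gene Ago4 (0.85, SE 0.13). The median, the mean and the test differed in sign for the decidua, p53, hypoxia, microRNA pathway, chromosome neighbour and housekeeping lists.

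The X-inactivation transcript Xist was between 2.48 and 2.72 in wildtype replicate 3 and knockout replicates 2 and 3, where Eif2s3y was between -5.42 and -5.21. In the other 6 arrays Xist was between -5.43 and -2.61 and Eif2s3y between 4.06 and 5.37. High Xist with low Eif2s3y is the female pattern and the reverse is the male one. Both genotypes held arrays of each pattern, with wildtype replicate 3 and knockout replicates 2 and 3 on the female side. The Eif2s3y covariate, with which 2 genes passed, thus adjusts for sex.

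Klhdc9, which rose, and Itln1, which fell, lie 9 gene records apart on chromosome 1 in the gene order of GRCm38.p6. Among random sets of 19 genes, 7.20% of 10000 draws held a pair as near.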
